A study of Homo sapiens with 18 samples.

How the data were processed

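RNA from 3 human colon cell lines was measured on 18 two-channel cDNA arrays. The labels describe the cells as exposed to 1 of 3 folic acid doses (10, 100 or 4000 ng/ml). There were 2 arrays (replicates A and B) in each of 9 groups of line and dose. Per the labels, channel 1 held RNA of the line and channel 2 a common reference made from RNA of the 3 lines. The deposited values are log ratios of the 2 channels and were used as log2 values. The base of the logarithm, the dyes, the direction of the ratio, the background correction and the normalization are not given in the sources used here. Base 10 was ruled out by the range of the values, from -7.08 to 2.71; natural logarithms remain possible, and p-values do not depend on that choice while folds do. The ratio was read as line over reference because the labels put the line in channel 1 and because APOA1, CDH17, GPC3, AFP and APOB, genes known in Caco-2, then came out highest in Caco-2. These genes are also among the largest rises of Caco-2 over HT29 given below, so their direction there is not an added result. If the ratio runs the other way, every higher and lower below is exchanged.

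All 2052 features had a value on all 18 arrays, so the filter (at least 14 arrays) removed nothing. The platform listed 1 gene symbol for 1247 features, several for 50 and none for 755. Features with the same symbol were averaged into 492 named genes (418 with 2 spots, 73 with more, 1 with 1); the other 805 features were tested as unnamed probes. Of the 1247 listed features, 1241 had a gene identifier found in the reference table, and 0 symbols changed. Duplicate spots of a clone are separate unnamed probes where no symbol is listed, so counts over all 1297 genes and probes count some clones more than once. Each array was centred on its median, since array medians before centring ranged from -2.11 to -0.04; changes are therefore relative to the typical feature of an array.

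Differences were tested with limma (version 3.58.1, R 4.3.3), with 1 mean per group, 9 residual degrees of freedom and empirical Bayes shrinkage (prior degrees of freedom 8.37, prior SD 0.228). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 1297 genes and probes; those under 0.05 after adjustment passed. Line contrasts averaged the 3 doses and pooled dose contrasts averaged the 3 lines, with equal weight; doses were also compared within each line, and the line by dose interaction was tested. Errors of changes are standard errors (SE) from this fit, and errors of levels are SD. The labels do not say that replicates A and B were separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. One variance per gene was shared by all groups, although the CCD841CoTr replicates at 10 and 100 ng/ml differed more than those of the other groups.

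The groups, contrasts, threshold, naming rule, 24 gene lists and the first set of alternative settings were fixed before the data were examined. Of the lists, 12 had at least 4 measured genes and were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 12 lists of a contrast), with an estimated correlation and limma's fry as alternatives. The genes named for a line contrast were the 10 largest rises and the 10 largest falls that passed and whose 6 arrays in 1 line all lay above the 6 of the other; 1 of these genes is not reported here. For pooled doses the same numbers applied to genes that passed and moved the same way in all 3 lines. For doses within a line and for the interaction they were the 5 of smallest p that passed. Where fewer than 5 passed, the 5 of smallest p were given as values. The 4 members of smallest p were named for each list that passed, as were members of the 2 folate lists with an adjusted p under 0.05 over the list alone. Other genes named were members of the fixed lists, or were chosen after their values were seen, as stated there.

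These settings were values as deposited, quantile normalization, array weights, robust empirical Bayes, a replicate block, 2 filters, each probe by itself, a 1.5-fold minimum, only the groups compared, and leaving out each array in turn. Chosen after the data were seen were named genes only, and fits without HT29, without CCD841CoTr or without both CCD841CoTr arrays at 100 ng/ml. The procedure was tested on simulated data of the same size. For the pooled contrast of 4000 and 10 ng/ml it recovered 73.1% of changes of 0.5 and 100% of changes of 1 (log2); for the same doses in HT29 it recovered 25.4% and 85.1%; for Caco-2 against CCD841CoTr, 70.1% and 100%. It called 1.09%, 0.456% and 0.638% of the unchanged ones. A simulated list shifted by 0.5 was called, and 0 of the others. These rates and list calls hold for the simulated data only. In the measured data the SD between replicates was 0.352 and 0.423 in CCD841CoTr at 10 and 100 ng/ml, against 0.201 at 4000 ng/ml. Duplicate spots of a clone and genes of a list may also vary together. The simulation therefore does not show that the rates carry over to the measured data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.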

Results

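The 18 arrays compared RNA of Caco-2 and HT29, established lines from colorectal cancers, and of CCD841CoTr, a transformed line from normal colon, with a common reference made from the 3 lines. Each line was exposed to 3 folic acid doses (10, 100 and 4000 ng/ml), with 2 arrays per line and dose, or 6 per line. Each array gave 2052 values, and 492 named genes and 805 unnamed probes were tested. Levels are log2 ratios to the reference with the median of the array set to 0. Across genes, arrays of the same line correlated with r between 0.869 and 0.93 in Caco-2, between 0.706 and 0.91 in HT29 and between 0.678 and 0.939 in CCD841CoTr; genes are not independent replicates. The SD between replicates (that of A minus B across genes, divided by the square root of 2) was 0.352 in CCD841CoTr at 10 ng/ml and 0.423 at 100 ng/ml, against 0.201 at 4000 ng/ml and 0.184 to 0.244 in the groups of the other lines.

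The first comparison asked how the lines differ, averaged over dose. AGR2, a protein of secretory epithelial cells, was the most strongly raised named gene in Caco-2 over CCD841CoTr, 94.9-fold (log2 6.57, SE 0.16, adjusted p = 1.36e-16). The epithelial keratin KRT19 was 39.2-fold higher (5.29, SE 0.11) and the epithelial adhesion molecule EPCAM 22.8-fold higher (4.51, SE 0.13; 1.88 to 5.94 over its 8 spots). SERPINA1, a secreted protease inhibitor, was 25.2-fold higher (4.66, SE 0.10), and APOA1, the main apolipoprotein of high-density lipoprotein, was 19.2-fold higher (4.26, SE 0.21). CCD841CoTr had the higher level of MMP1, an interstitial collagenase, with a Caco-2 difference of -3.04 (SE 0.28), and of the fructose transporter SLC2A5 (-2.86, SE 0.18). The naming rule required that each gene separate all 6 arrays of Caco-2 from all 6 of CCD841CoTr, so the separation of these 7 genes is not an added result.

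Other leading genes higher in Caco-2 were the retinaldehyde dehydrogenase ALDH1A1 (4.18), GRAMD2B (2.98), MPP1 (2.88), the intestinal cadherin CDH17 (2.76; 1.48 to 4.06 over its 10 spots) and ANXA13 (2.54). Lower were the metallothionein MT2A (-2.32), the MHC class I light chain B2M (-2.06), KLHL24 (-1.85), TGFB2 (-1.55), IGFBP5 (-1.54), ACSL4 (-1.46) and the stress-induced gene GADD45A (-1.45). Among 9 hepatocyte-type secreted proteins, 8 were higher in Caco-2, 0 were lower and 1 did not pass (limma camera, adjusted p = 2.31e-05; adjusted p = 0.245 with an estimated correlation); besides SERPINA1 and APOA1, APOH was higher by 2.47 and APOA2 by 1.63. All 9 passed when adjusted over the list alone. Of 12 enterocyte genes, 6 were higher, 4 lower and 2 did not pass (adjusted p = 0.173 for the list): CDH17, APOA1, the fatty acid binding protein FABP1 (1.56) and sucrase-isomaltase SI (1.20) were higher, and the peptide transporter SLC15A1 (-0.78) was lower. Of 4 fibroblast and mesenchymal markers, MMP1 and IGFBP5 were lower, TIMP3 was lower (-0.47) but changed sign as deposited, and FN1 was higher (0.38). Adjusted over the list alone, 10 of the enterocyte genes and 4 of these markers passed.

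Over all genes and probes, limma with Benjamini-Hochberg adjustment called 838, of which 362 were higher and 476 lower in Caco-2; 322 were named genes. With values as deposited the count was 866, with 831 higher and 35 lower, and the median of all features shifted by 0.60. The split by direction therefore depends on the scaling.

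**Figure D1:**
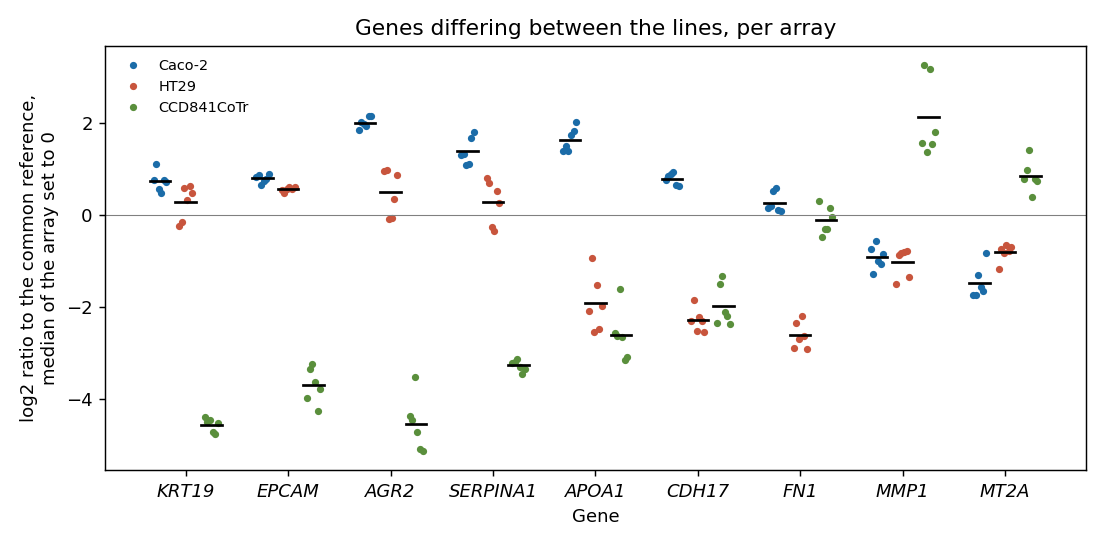
Log2 ratio to the reference (vertical axis, array median set to 0) of 9 genes on each of the 18 arrays, coloured by line, with the mean of 6 arrays as a bar. KRT19 averaged 0.73 in Caco-2, 0.27 in HT29 and -4.57 in CCD841CoTr, and MMP1 averaged -0.92, -1.03 and 2.12.

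Against CCD841CoTr, AGR2 was also the most strongly raised named gene in HT29, 33.3-fold higher (5.06, SE 0.16, adjusted p = 1.19e-14), KRT19 28.6-fold (4.84, SE 0.11), EPCAM 19.3-fold (4.27, SE 0.13; 1.74 to 5.97 over its spots) and SERPINA1 11.7-fold (3.55, SE 0.10). MMP1 was lower by a log2 difference of -3.15 (SE 0.28) and fibronectin FN1 by -2.51 (SE 0.15; -3.80 to -0.20 over its 12 spots). By the naming rule, all 6 HT29 arrays lay beyond all 6 of CCD841CoTr for these genes and for the others named next. ALDH1A1 (2.80), the nuclear receptor PPARG (2.32), MAL2 (2.16), APOH (2.12), ANXA13 (1.95) and CTNNBL1 (1.76) were higher. MT2A (-1.66), the kinase MAP4K4 (-1.65), TMEM98 (-1.50), SLC2A5 (-1.39), IGFBP5 (-1.32), TGFB2 (-1.16) and the lipid droplet protein PLIN2 (-1.12) were lower.

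All 4 measured fibroblast and mesenchymal markers were lower in HT29, FN1, MMP1, IGFBP5 and TIMP3 (-0.96; -0.27 and not called as deposited), also when adjusted over the list alone (camera, adjusted p = 0.000654; adjusted p = 0.0488 with an estimated correlation). Of 8 cytosolic ribosomal protein genes, 6 were higher in HT29, 1 was lower and 1 did not pass, with RPL31 at 1.40, RPS3 at 1.38, RPS12 at 1.19 and RPL3 at 0.86 (camera, adjusted p = 0.0192; adjusted p = 0.247 with an estimated correlation). Of these, 7 passed when adjusted over the list alone. Of 4 goblet and secretory markers, 3 were higher and 1 did not pass: AGR2, the trypsin inhibitor SPINK1 (1.04) and REG4 (0.80). Of the 4, 3 passed when adjusted over the list alone, while the list did not pass (adjusted p = 0.0655). Limma with Benjamini-Hochberg adjustment called 636 genes and probes, 346 higher and 290 lower in HT29, of which 268 were named genes. As deposited 998 were called, 973 higher and 25 lower, with a median shift of 0.69.

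Between the cancer lines, Caco-2 had the higher level of APOA1, 11.9-fold (3.57, SE 0.21, adjusted p = 4.48e-10), CDH17, 8.4-fold (3.07, SE 0.16; 1.42 to 4.38 over its spots), the fetal liver protein AFP, 7.55-fold (2.92, SE 0.27), and FN1, 7.4-fold (2.89, SE 0.15; 0.36 to 4.23 over its spots). HT29 had the higher level of B2M (-2.12, SE 0.16) and KLHL24 (-1.90, SE 0.12), which in HT29 averaged -0.25 and -0.52 at 10 ng/ml, -1.34 and -1.16 at 100 ng/ml and 2.02 and 2.06 at 4000 ng/ml, against -1.998 and -1.859 in Caco-2 at 100 ng/ml. By the naming rule, the 6 arrays of 1 line lay beyond the 6 of the other for these genes and for those named next. Caco-2 was higher in the glypican GPC3 (2.81), TMEM98 (2.46), NAALAD2 (2.23), APOB (2.21; 7 of its 8 spots higher, the lowest at -0.09), GRAMD2B (2.20) and PLIN2 (2.14). It was lower in SPG21 (-1.68), PLAAT3 (-1.56), SLC2A5 (-1.46), MAL2 (-1.43), the acyl-CoA synthetase ACSL1 (-1.31), ANXA2 (-1.31), the protease CTSE (-1.30) and RAB11A (-1.28).

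Of 9 hepatocyte-type secreted proteins, 8 were higher in Caco-2 than in HT29, 0 were lower and 1 did not pass (camera, adjusted p = 1.27e-06; adjusted p = 0.143 with an estimated correlation), with APOA2 at 1.35 and SERPINA1 at 1.11. All 9 passed when adjusted over the list alone. Limma with Benjamini-Hochberg adjustment called 665 genes and probes between these lines, 252 higher and 413 lower in Caco-2, of which 259 were named. As deposited it called 440, 210 higher and 230 lower.

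The folate genes measured were few: 3 of the enzymes (SHMT2, MTHFD2 and GLDC) and 4 of the transport and binding genes (FOLR1, FOLR2, FOLR3 and the efflux pump ABCC2). ABCC2 was higher in Caco-2 than in CCD841CoTr (0.74, SE 0.12, adjusted p = 2.58e-05) and than in HT29 (0.76, SE 0.12). Caco-2 was lower than HT29 in FOLR2 (-0.76, SE 0.11), in SHMT2 (-0.48, SE 0.10), the mitochondrial serine hydroxymethyltransferase, and in MTHFD2 (-0.44, SE 0.13; not called as deposited), a mitochondrial folate enzyme. MTHFD2 was also higher in HT29 than in CCD841CoTr (0.48, SE 0.13), and GLDC, of the glycine cleavage system, was higher in Caco-2 than in CCD841CoTr (0.47, SE 0.19). The GLDC call was lost in 11 of 29 alternatives, with the value at 0.21 without CCD841CoTr 100 A, and the 2 CCD841CoTr arrays at 100 ng/ml differed widely (mean -0.21, SD 1.13, n = 2). Caco-2 was lower than CCD841CoTr in FOLR1 (-0.42), FOLR2 (-0.52), FOLR3 (-0.47) and SHMT2 (-0.42), but these 4 changed sign with values as deposited (0.33, 0.22, 0.27 and 0.32). The FOLR1 call was also lost in 9 of 29 alternatives, and its CCD841CoTr arrays at 100 ng/ml differed widely (mean 0.06, SD 0.83, n = 2). Adjusted over the list alone, 2, 1 and 2 enzymes and 4, 0 and 2 transport genes passed in the contrasts of Caco-2 with CCD841CoTr, HT29 with CCD841CoTr and Caco-2 with HT29. For the transport list, camera gave adjusted p = 0.793, 0.886 and 0.929.

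The dose comparisons asked which genes differ with folic acid. Over all genes and probes, 0 folate enzymes and 0 transport genes passed limma with Benjamini-Hochberg adjustment in any of the pooled or within-line dose contrasts. At an unadjusted p under 0.05 the enzymes with pooled values were MTHFD2 and GLDC between 4000 and 10 ng/ml and MTHFD2 and SHMT2 between 100 and 10 ng/ml. Adjusted over the list alone, MTHFD2 (0.45, SE 0.13, adjusted p = 0.00743) and SHMT2 (0.27, SE 0.10, adjusted p = 0.0218) passed limma's test for 100 against 10 ng/ml over the 3 lines. At the lowest over the alternatives these pooled values were 0.30 and 0.14. In CCD841CoTr, adjusted over the list alone, MTHFD2 passed at 100 ng/ml (0.75, SE 0.22, adjusted p = 0.01) and at 4000 ng/ml (0.71, SE 0.22, adjusted p = 0.0157), and SHMT2 at 100 ng/ml (0.53, SE 0.17, adjusted p = 0.0102). Without CCD841CoTr 10 A the MTHFD2 values were 0.35 and 0.31, as the 2 arrays at 10 ng/ml differed (mean -0.78, SD 0.57, n = 2). The changes of MTHFD2 and SHMT2 in Caco-2 at 100 ng/ml were 0.19 and 0.09.

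Averaged over the lines, UBE2L6, an E2 enzyme that conjugates ubiquitin-like ISG15, rose by 1.13 between 10 and 4000 ng/ml (SE 0.12, adjusted p = 6.07e-05). KLHL24 rose by 1.01 (SE 0.12), B2M by 1.06 (SE 0.16) and catalase CAT by 0.48 (SE 0.11, adjusted p = 0.0408). The transcription factor TFEC fell (-0.84, SE 0.19, adjusted p = 0.0342). The naming rule picked B2M, CAT and TFEC because their mean changes had the same sign in all 3 lines. For B2M these were 2.27 in HT29, 0.67 in CCD841CoTr and 0.25 in Caco-2. The CCD841CoTr value of B2M rests on 1 array: 10 A was at -1.01, while 10 B was at 0.18 and the 4000 ng/ml arrays were at 0.33 and 0.19. ANXA13 fell (-0.59, SE 0.12, adjusted p = 0.025) but was 0.08 as deposited, and SAT1, a polyamine acetyltransferase, rose (0.53, SE 0.12, adjusted p = 0.0342). They and UBE2L6 and KLHL24 did not move the same way in all 3 lines. The calls of CAT, SAT1 and TFEC were lost in 15, 15 and 12 of 31 alternatives, with TFEC at -0.17 as deposited and SAT1 at 0.29 without HT29; ANXA13 was lost in 8 and reversed in 2. Without HT29, UBE2L6, KLHL24 and B2M were at 0.16, 0.22 and 0.46 and were not called. For 100 against 10 ng/ml, ANXA13 fell (-0.77, SE 0.12, adjusted p = 0.00472) but was 0.08 without HT29 and averaged 0.36 and 0.88 at 10 and 100 ng/ml in Caco-2. The named genes ERN1 (-0.56; 0.01 as deposited), REG4 (0.56), SERPINA1 (0.42) and TRAPPC4 (0.41) followed with adjusted p from 0.0708 to 0.0967; without HT29, REG4, SERPINA1 and TRAPPC4 were at 0.06, 0.11 and 0.22. For 4000 against 100 ng/ml, UBE2L6 (1.41), KLHL24 (1.09) and B2M (1.12) passed, with changes of 3.94, 3.22 and 3.36 in HT29 and pooled values of 0.15, 0.02 and 0.00, not called, without it. FTL (0.45) and S100A10 (-0.47) had an adjusted p of 0.0739.

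Cytosolic ribosomal protein genes passed as a list for 100 against 10 ng/ml (camera, adjusted p = 0.0103; adjusted p = 0.299 with an estimated correlation). Of the 8 members, 0 passed by limma with Benjamini-Hochberg adjustment and 2 did when adjusted over the list alone. The values of RPS3, RPL27, RPL35A and RPL3 were 0.43, 0.42, 0.24 and 0.20. Without HT29 those of RPS3 and RPL27 were 0.24 and 0.15, and without CCD841CoTr that of RPL35A was -0.07. Leaving out single arrays also moved values by over 1.5 times, RPL35A to 0.13 without CCD841CoTr 10 A and RPL3 to 0.10 without CCD841CoTr 100 A. Limma with Benjamini-Hochberg adjustment called 16 genes and probes for 4000 against 10 ng/ml (11 higher and 5 lower, 7 of them named), 2 for 100 against 10 and 4 for 4000 against 100. Leaving out 1 array moved the first count to between 6 (without Caco-2 4000 B) and 64 (without CCD841CoTr 10 B), by over 1.5 times in 14 of 18 omissions, and the others to as many as 52 and 56 (without CCD841CoTr 100 B and 100 A). A limma fit of line plus dose called 0, 0 and 0, with 156, 113 and 92 at an unadjusted p under 0.05. Quantile normalization called 15 for the first, with 12 higher and 3 lower. As deposited, 1181 and 1134 were called against 10 ng/ml and all were higher, with median shifts of 0.66 and 0.58. Without the HT29 arrays, an alternative chosen after the data were seen, limma called 0, 0 and 0, with 160, 77 and 50 at an unadjusted p under 0.05.

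In Caco-2, 0 genes and probes passed limma with Benjamini-Hochberg adjustment among the 3 doses, between 4000 and 10 ng/ml or between 100 and 10 ng/ml; 72, 92 and 47 had an unadjusted p under 0.05. The named genes of smallest p between 4000 and 10 ng/ml were the translation factor EIF4A2 (0.92, SE 0.21, adjusted p = 0.2), superoxide dismutase SOD1 (0.86, SE 0.21), AFP (1.83, SE 0.47), SERPINA1 (0.65, SE 0.17) and SAT1 (0.76, SE 0.20), each higher on both 4000 ng/ml arrays than on both 10 ng/ml arrays. AFP averaged -0.57 (SD 0.07, n = 2), 0.04 (SD 0.18) and 1.26 (SD 0.07) at 10, 100 and 4000 ng/ml. For 100 against 10 ng/ml the values were CGA -0.56, GRHL2 -0.61, CAT 0.50, PAFAH1B2 0.56 and PFKFB2 0.46, with an adjusted p of 0.999 (limma). Over the alternatives CGA ranged from -0.755 to -0.04 and GRHL2 from -0.92 to -0.08. CAT ranged from 0.34 to 1.03, PAFAH1B2 from 0.34 to 1.09 and PFKFB2 from 0.29 to 0.99. These alternatives include values as deposited, where the median of all features shifted by 0.52. Among the 3 doses, CDH3 also had an adjusted p of 0.331. Hepatocyte-type secreted proteins passed as a list for 4000 against 10 ng/ml (camera, adjusted p = 0.0322; adjusted p = 0.496 with an estimated correlation) and so did ribosomal protein genes (camera, adjusted p = 0.0352; adjusted p = 0.496 with an estimated correlation), with 0 members of either passing by limma and 2 and 0 when adjusted over the list alone. AFP, SERPINA1, APOA2 (0.45) and APOB (-0.59, 7 of 8 spots) led the first list, and RPS12 (0.49), RPL3 (0.30), RPL11 (0.32) and RPL37A (0.33) the second. At the lowest over the alternatives SERPINA1 and APOA2 were at 0.34 and 0.08. RPS12, RPL3, RPL11 and RPL37A were then at 0.169, 0.146, 0.208 and 0.145. Quantile normalization called 4 among the doses and 12 for 4000 against 10, array weights 13 and 24, and a fit of the groups compared alone 1 and 1; as deposited it was 0 and 0.

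In HT29, UBE2L6 rose 8.48-fold between 10 and 4000 ng/ml (3.08, SE 0.21, adjusted p = 5.6e-08), from -0.77 (SD 0.15, n = 2) to 2.32 (SD 0.13, n = 2). KLHL24, a substrate adaptor of a ubiquitin ligase, rose 6-fold (2.58, SE 0.20), B2M 4.81-fold (2.27, SE 0.27) and DDIT3, a stress-induced transcription factor, 2.68-fold (1.42, SE 0.23). ANXA13 fell by a log2 change of -2.17 (SE 0.21). Both arrays at 4000 ng/ml lay beyond both at 10 ng/ml for these 5 genes. Chosen after their values were seen, the glucuronosyltransferases UGT2A3 (1.59, adjusted p = 0.00141) and UGT2B7 (1.43, adjusted p = 0.00692) and the fibrinogen chain FGG (1.20, adjusted p = 0.00809) also rose, and the heat shock family gene HSPA1L fell (-1.31, adjusted p = 0.00801).

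At 100 against 10 ng/ml in HT29, ANXA13 was again lower (-2.47, SE 0.21, adjusted p = 1.63e-06), and the ferritin light chain FTL fell (-0.97, SE 0.18, adjusted p = 0.00403; -0.08 as deposited). The secreted lectin REG4 (1.56, SE 0.22), the cadherin CDH3 (1.14, SE 0.19; 0.96 and not called without HT29 10 A) and SERPINA1 (1.05, SE 0.17) rose. Both arrays of 1 dose lay beyond both of the other for these 5 genes. Of 4 goblet and secretory markers, 3 rose and 1 did not pass: REG4, SPINK1 (1.39, adjusted p = 0.0046) and AGR2 (1.04, adjusted p = 0.0367); 3 passed when adjusted over the list alone, and the list itself was not tested for this contrast. UBE2L6 was lower at 100 than at 10 ng/ml (-0.85, adjusted p = 0.0266) but changed sign as deposited, and B2M was lower (-1.09, adjusted p = 0.0257; -0.21 as deposited). Among the 3 doses, UBE2L6, KLHL24, ANXA13, B2M and HERC6, a ubiquitin ligase family gene (adjusted p = 0.00059), had the smallest p.

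**Figure D2:**
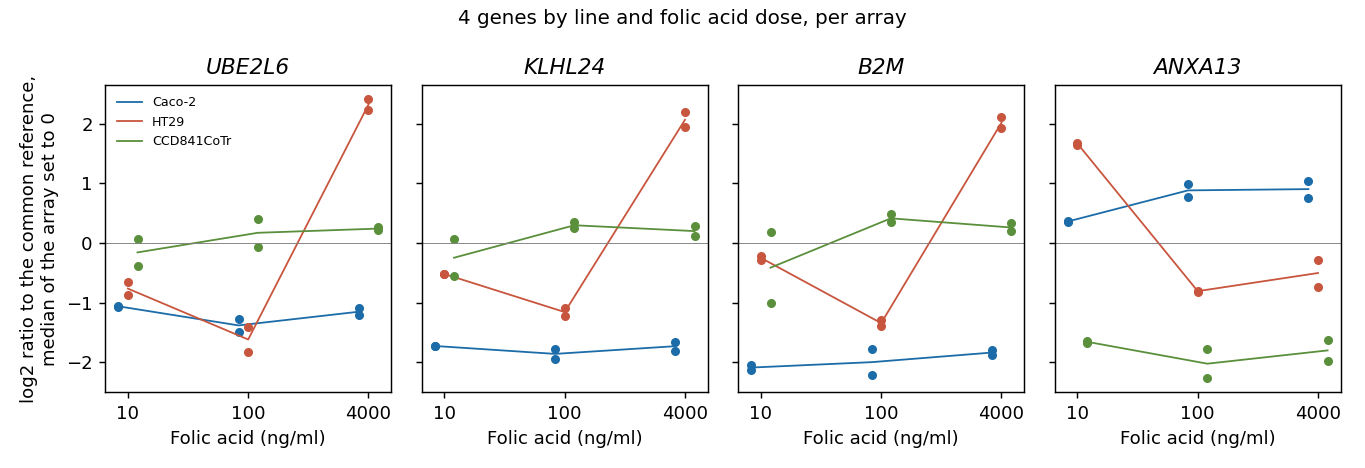
Log2 ratio to the reference (vertical axis, array median set to 0) of UBE2L6, KLHL24, B2M and ANXA13 against folic acid dose (horizontal axis, evenly spaced categories in ng/ml), with 1 point per array and lines through group means. In HT29 the means of UBE2L6 were -0.77, -1.62 and 2.32 at 10, 100 and 4000 ng/ml, and those of ANXA13 were 1.67, -0.81 and -0.50; the fall of UBE2L6 at 100 ng/ml changes sign as deposited.

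Limma with Benjamini-Hochberg adjustment called 139 genes and probes among the doses in HT29 (50 named), 53 between 4000 and 10 ng/ml (39 higher and 14 lower, 20 named) and 62 between 100 and 10 ng/ml (42 higher and 20 lower, 21 named). Quantile normalization gave 32 higher and 6 lower for the former pair; values as deposited gave 62 and 1, and 1007 and 1 for the latter, with median shifts of 0.30 and 0.92. The counts rested on single arrays: without HT29 4000 A, 10 A or 10 B the 53 became 13, 16 or 23, and without HT29 10 A, 100 A, 100 B or 10 B the 62 became 6, 19, 24 or 25. For 4000 against 10 ng/ml, 0 lists passed camera or camera with an estimated correlation, and fry called 1.

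In CCD841CoTr, the mitochondrial iron importer SLC25A37 rose 2-fold between 10 and 4000 ng/ml (SE 0.20 on the log2 scale, adjusted p = 0.0262), PHLDA1 by a log2 change of 1.02 (SE 0.21), the lysosomal precursor PSAP by 1.02 (SE 0.21) and the translation factor EIF4B by 1.07 (SE 0.24). ALG8, an enzyme of protein N-glycosylation, fell (-1.31, SE 0.29, adjusted p = 0.0282) but was 0.28 as deposited. MAT2A, which makes S-adenosylmethionine, rose by 0.86 (SE 0.20, adjusted p = 0.0287), as 1 of 8 genes of the methionine cycle and methylation, with 0 lower and 7 that did not pass; 2 passed when adjusted over the list alone (camera, adjusted p = 0.712). Of 9 hepatocyte-type secreted proteins 0 passed by limma with Benjamini-Hochberg adjustment and 3 when adjusted over the list alone, while the list passed as lower (camera, adjusted p = 0.0337; adjusted p = 0.788 with an estimated correlation). Its leading members ALB (-0.74), APOB (-0.79), APOA1 (-0.99) and APOH (-0.68) all changed sign as deposited, at 0.86, 0.81, 0.60 and 0.91. Without CCD841CoTr 10 A, APOB, APOA1 and APOH were at -0.26, -0.47 and -0.26, and without 10 B at -1.31, -1.51 and -1.11. Both 4000 ng/ml arrays lay beyond both 10 ng/ml arrays for the 5 genes of smallest p and these 4 members. APOB, APOA1 and APOH were already low at 10 ng/ml, averaging -1.83, -2.13 and -1.94. Of genes outside the list that were low there, AGR2 fell from -4.13 to -5.12 and EPCAM from -3.44 to -4.03. KRT19 was at -4.60 and -4.65. Whether genes of low level fell as a group was not tested.

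Limma with Benjamini-Hochberg adjustment called 42 genes and probes between 4000 and 10 ng/ml in CCD841CoTr, 24 higher and 18 lower (15 named); quantile normalization gave 48 higher and 10 lower, and values as deposited 1268 and 0, with a median shift of 1.53. The call rested on the variance shared with other groups and on single arrays: it was 0 in a fit of the groups compared alone (315 at an unadjusted p under 0.05) and without CCD841CoTr 4000 A, and 271 without CCD841CoTr 100 A. SLC25A37, PHLDA1, PSAP and EIF4B were each lost in 4 of 28 alternatives and ALG8 in 6. Among the 3 doses 0 were called (291 at an unadjusted p under 0.05, 1260 as deposited, 0 by quantile normalization, 282 without CCD841CoTr 100 A); SLC25A37 and PHLDA1 had an adjusted p of 0.0544, and PSAP, CHMP7 and ERN1 of 0.0596. Between 100 and 10 ng/ml 0 were called by limma (99 at an unadjusted p under 0.05, and 0 as deposited and by quantile normalization). ERN1 (-0.90), RPL35A (0.85), MAT2A (0.69), MTHFD2 (0.75) and EDN1 (0.75) had an adjusted p of 0.469. Over the alternatives RPL35A, MAT2A, MTHFD2 and EDN1 fell to as low as 0.51, 0.43, 0.35 and 0.40, and ERN1 reached -0.60.

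The interaction test asked whether the dose response differed between lines. UBE2L6 (adjusted p = 9.73e-07), KLHL24 (adjusted p = 3.38e-06), ANXA13 (adjusted p = 3.41e-05), B2M (adjusted p = 9.26e-05) and UGT2A3 (adjusted p = 0.00306) led 54 genes and probes called by limma with Benjamini-Hochberg adjustment, 20 of them named; 1229 were called as deposited. The HT29 response of UBE2L6 to 4000 against 10 ng/ml exceeded that of Caco-2 by 3.17 (SE 0.30) and that of CCD841CoTr by 2.68 (SE 0.30), and ANXA13 differed by -2.71 (SE 0.30) and -2.03 (SE 0.30). In Caco-2 the changes were -0.09 for UBE2L6 and 0.25 for B2M. Pairwise tests of the 4000 against 10 ng/ml response called 11 genes and probes between HT29 and Caco-2, 79 between HT29 and CCD841CoTr and 10 between CCD841CoTr and Caco-2; for 100 against 10 ng/ml they called 2, 19 and 0.

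**Figure D3:**
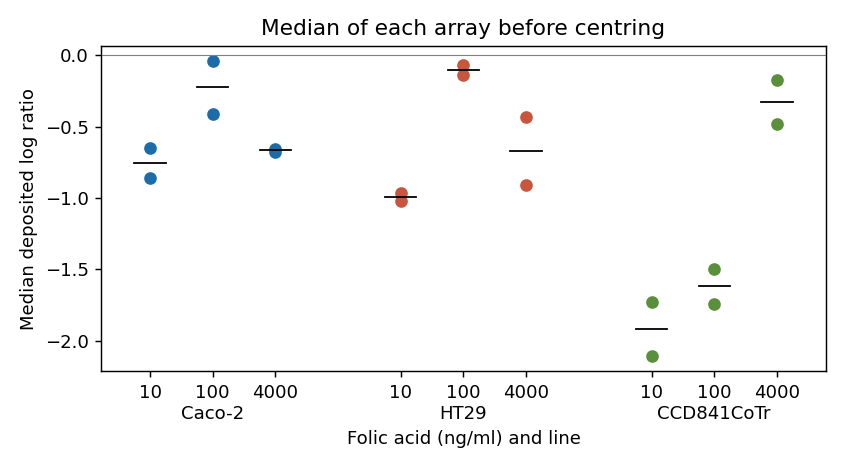
Median deposited log ratio of each array (vertical axis) by line and folic acid dose in ng/ml (horizontal axis), with the mean of the 2 arrays as a bar. CCD841CoTr averaged -1.92, -1.62 and -0.33 at 10, 100 and 4000 ng/ml, HT29 -0.99, -0.11 and -0.67, and Caco-2 -0.75, -0.23 and -0.66.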

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

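All tests below except the interaction test were chosen after the patterns they weigh were seen; for the tests of an interferon-type and a stress response, the expected values were written down before the measured ones were seen.

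The interaction test picked out 20 named genes whose dose response differed between the lines (adjusted p from 9.73e-07 to 0.0458). The values that follow are the 4000 minus 10 ng/ml response in HT29 minus the mean response of Caco-2 and CCD841CoTr (log2). UBE2L6 was at 2.93 (SE 0.26), KLHL24 at 2.36 (SE 0.25), B2M at 1.80 (SE 0.33), UGT2A3 at 1.95 (SE 0.32) and DDIT3 at 1.58 (SE 0.28). UGT2B7 was at 1.48 (0.96 as deposited), HERC6 at 1.15 (0.63), the nuclease REXO2 at 1.04 (0.52), REG4 at 0.74 (0.22) and SAT1 at 0.73 (0.21). The iron exporter SLC40A1 was at 0.53 (0.01 as deposited) and SERPINA1 at 0.46, which changes sign as deposited. ANXA13 was at -2.37 (SE 0.26), HSPA1L at -1.85 (SE 0.33), the helicase DDX6 at -0.80 (-1.31 as deposited) and the deubiquitinase USP7 at -0.69 (-1.21). PHLDA1 was at -0.40 (SE 0.25), FTL at -0.32 (SE 0.22) and SLC25A37 at -0.27 (SE 0.24), each within 2 SE of 0. As deposited they were at -0.92, -0.84 and -0.79. The interaction calls of these 3 genes need not reflect a different HT29 response at 4000 ng/ml. CDH3 was at 0.03 (SE 0.23), which also changes sign as deposited (interaction adjusted p = 0.00783). Leaving out single arrays moved the 54 interaction calls to between 19 (without Caco-2 4000 A) and 213 (without CCD841CoTr 100 A).

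UBE2L6, KLHL24 and B2M stood at 2.32, 2.06 and 2.02 in HT29 at 4000 ng/ml and at -1.62, -1.16 and -1.34 at 100 ng/ml. Mixing with CCD841CoTr RNA cannot raise a gene above its level there, yet the lowest of the 3 differences from CCD841CoTr at 4000 ng/ml was 1.76 (SE 0.27); all 8 spots rose, by 3.19 to 4.18, which argues against single spots; and the lowest rise over 3 genes and 3 scalings was 2.66, which argues against the centring. An interferon-type response may contribute but is not established. OAS1, ICAM1 and ZNFX1 changed on average by 0.30 (95% interval 0.09 to 0.51) between 100 and 4000 ng/ml. That mean rests mainly on ZNFX1 (limma, 0.66, adjusted p = 0.115), with OAS1 at 0.21 (adjusted p = 0.655) and ICAM1 at 0.04 (adjusted p = 0.95). HERC6, B2M and UBE2L6 were not in this set, so the mean does not weigh them. HERC6 rose by 1.58 between these doses in HT29 (limma, adjusted p = 0.000174). The mean of OAS1, ICAM1 and ZNFX1 also rests on the centring. The HT29 array medians before centring averaged -0.11 at 100 and -0.67 at 4000 ng/ml. That fall is larger than 0.30, so the mean changes sign as deposited. The rise expected of a stress response with DDIT3 was not seen. ATF3, ERN1, HSP90B1 and SYVN1 averaged -0.12 (95% interval -0.37 to 0.13), where an interval above 0 was expected. By the rule written beforehand the prediction failed. An interval that holds 0, over members of both signs, cannot decide for or against such a response. ERN1 (0.37) and ATF3 (0.14) lay above 0, also only as centred, and HSP90B1 (-0.42) and SYVN1 (-0.55) below. Of the other stress genes in the fixed list, HSPD1 (-1.04) and HSPE1 (-1.06) fell, while DDIT3 itself rose (1.37). HSPA4 (-0.43) did not pass (limma, adjusted p = 0.386). As these genes went both ways, a response of some of them is not excluded. An unrecorded batch shared by the HT29 arrays at 4000 ng/ml was not tested and cannot be told apart from the dose.

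The CCD841CoTr arrays split across their labels: 100 A had a Spearman correlation across genes of 0.767 and 0.79 with the 4000 ng/ml arrays and 0.543 with 100 B, while 100 B had 0.768 and 0.876 with the 10 ng/ml arrays. The overall level of the arrays is not excluded as a cause. The median of 100 A minus that of the lower 4000 ng/ml array was -1.02, while the 4000 ng/ml arrays differed by 0.31. But the order of the medians follows the split. Those of 100 A (-1.50) and the 4000 ng/ml arrays (-0.17 and -0.48) lay above those of 100 B (-1.74) and the 10 ng/ml arrays (-2.11 and -1.73). A mislabelled array or an unrecorded batch could account for it: the difference between the 100 ng/ml arrays correlated across genes with the 4000 minus 10 ng/ml difference at r = 0.65, against 0.08 in Caco-2 and 0.10 in HT29. That value restates the split, so these cannot be told apart from ordinary variation between samples. No biological explanation was tested.

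Array medians before centring were lower at 10 than at 4000 ng/ml, by 0.67 on average over the lines (exact two-sided permutation within lines, p = 0.0278, 216 arrangements). The average was carried by CCD841CoTr, with means of -1.92 and -0.33 at 10 and 4000 ng/ml, against -0.99 and -0.67 in HT29 and -0.75 and -0.66 in Caco-2. The arrays did not overlap in 2 of the 3 lines, HT29 and CCD841CoTr, and did in Caco-2. A difference in the scaling of arrays between doses could account for the 0.67, and a change in total signal would give the same, so the 2 cannot be told apart. No biological explanation was tested.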

How the results depend on the processing

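Alternatives chosen after the data were seen are named genes only, the fits without HT29 or CCD841CoTr and the fit without both CCD841CoTr arrays at 100 ng/ml. Both filters and robust empirical Bayes left every named gene's direction and call as they were; the filters removed nothing and so test nothing. Unless a cause is given below, the cause was not tested.

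As deposited, calls were 998 for HT29 against CCD841CoTr, 440 for Caco-2 against HT29, 1181 and 1134 for pooled 4000 and 100 against 10 ng/ml, 898 among doses in HT29, 1008 for 100 against 10 ng/ml in HT29, 1260 among doses in CCD841CoTr, 1268 for 4000 against 10 ng/ml there and 1229 for the interaction; array medians were not removed, and these counts include their shifts. Among the changes that reversed as deposited were SHMT2 0.32, FOLR1 0.33, FOLR2 0.22, FOLR3 0.27 and TIMP3 0.27 (Caco-2 against CCD841CoTr), ANXA13 0.0777 (pooled 4000 against 10), ERN1 0.01 (pooled 100 against 10), UBE2L6 0.03 (100 against 10 in HT29), and ALG8 0.28, ALB 0.86, APOB 0.81, APOA1 0.60 and APOH 0.91 (CCD841CoTr). Quantile normalization gave 4 calls among doses in Caco-2 and 12 for 4000 against 10 ng/ml. Each probe by itself gave 1324, 998 and 1039 for the line contrasts, 36 and 12 for pooled 4000 against 10 and 100, 73 in CCD841CoTr and 100 for the interaction; more probes than genes are counted.

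Array weights gave 34 for pooled 4000 against 10, 13 and 24 in Caco-2 (among doses, 4000 against 10), 232, 109 and 149 in HT29 (among doses, 4000 and 100 against 10), 11 in CCD841CoTr and 153 for the interaction. A 1.5-fold minimum gave 517, 343 and 323 for the lines and 10 for pooled 4000 against 10, by construction fewer. Only the groups compared gave 1 and 1 in Caco-2, 98 for 100 against 10 in HT29 and 0 for CCD841CoTr. Named genes only, with fewer tests, gave 335, 279 and 281 for the lines, 8 for pooled 100 against 10, 66, 22 and 27 in HT29 and 12 among doses in CCD841CoTr. Without both CCD841CoTr arrays at 100 ng/ml, pooled 4000 against 10 gave 58. Without CCD841CoTr the pooled contrasts (4000 against 10, 100 against 10, 4000 against 100) gave 79, 80 and 98; without HT29 they gave 0, 0 and 0 (limma; 160, 77 and 50 at an unadjusted p under 0.05), and ANXA13 reversed to 0.199 for 4000 and 0.0774 for 100 against 10 ng/ml.

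Lists called with an estimated correlation, by fry and as deposited were 0, 7 and 2 for Caco-2 against CCD841CoTr, 1, 7 and 4 for HT29 against CCD841CoTr, 0, 8 and 2 for Caco-2 against HT29, and 0, 3 and 2 for pooled 100 against 10; fry called 1 for pooled 4000 against 100 and 1 for HT29. For 4000 against 10 ng/ml in Caco-2 these were 0, 0 and 1, and in CCD841CoTr 0 with an estimated correlation and 3 by fry. Fry tests each list alone and does not compare it with other genes.

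The replicate letters do not pair the arrays: deviations of A from B correlated between -0.203 and 0.243 across 36 pairs of groups. With the letter as a block the counts were 842, 637 and 665 for the lines, 16, 3 and 4 for pooled doses (4000 and 100 against 10, 4000 against 100), 0, 0 and 0 in Caco-2 (among doses, 4000 and 100 against 10), 142, 51 and 63 in HT29, 0, 50 and 0 in CCD841CoTr and 49 for the interaction, and all lists passed or failed as without it.

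Leaving out 1 array at a time, with the lone array of a group assumed to vary like the other groups, gave 785 to 880, 548 to 726 and 573 to 769 for the lines, 6 to 64, 2 to 52 and 3 to 56 for the pooled doses (4000 against 10, 100 against 10, 4000 against 100), 0 to 1, 0 to 1 and 0 to 2 in Caco-2, 53 to 198, 13 to 74 and 6 to 93 in HT29, 0 to 282, 0 to 271 and 0 to 151 in CCD841CoTr, and 19 to 213 for the interaction. For pooled 4000 against 10 ng/ml, 14 of the 18 omissions moved the count by over 1.5 times, from 6 without Caco-2 4000 B to 64 without CCD841CoTr 10 B. Of the gene results in these fits, 2839 kept direction and side of the threshold, 72 no longer passed and 59 newly passed. Signal over background was not analysed here, so what array depth limits is unknown.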

Other observations

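Of the tests here, the splits of the pooled doses in a fit of 9 groups were chosen after the result was seen; the other splits were not.

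Of the iron and heme genes 3 were measured, SLC40A1, HEPH and FTL, too few for a list test. In Caco-2 and in HT29, 2 of the 3 were higher than in CCD841CoTr, 0 lower and 1 did not pass (2 passed when adjusted over the list alone, in each). The iron exporter SLC40A1 was higher than in CCD841CoTr by 1.24 (SE 0.10) in Caco-2 and by 1.53 (SE 0.10) in HT29, and the ferroxidase HEPH was higher in Caco-2 than in HT29 by 0.82 (SE 0.12). Of 6 cholesterol and fatty acid synthesis genes, 4 were higher in HT29 than in CCD841CoTr, 0 lower and 2 did not pass: SQLE (0.84), ACSL1 (0.56), SCD (0.55) and FASN (0.40); 5 passed when adjusted over the list alone and camera gave adjusted p = 0.163. The glutathione transferase GSTA1 was higher in Caco-2 than in CCD841CoTr by 1.32 (SE 0.11), among 7 metallothionein and oxidative stress genes of which 2 were higher, 2 lower and 3 did not pass (4 passed when adjusted over the list alone; camera, adjusted p = 0.945). In HT29 against CCD841CoTr, CAT (1.14, SE 0.11) was the 1 of these 7 that was higher, with 4 lower and 2 that did not pass (5 passed when adjusted over the list alone; camera, adjusted p = 0.237). MAT2A was lower in Caco-2 than in HT29, at -0.84 (SE 0.11, adjusted p = 1.34e-05). LCP1, the only white blood cell marker measured, was higher in Caco-2 than in CCD841CoTr by 0.46 (SE 0.11), and 0 endothelial markers were measured.

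ODC1, the first enzyme of polyamine synthesis, passed for 100 against 10 ng/ml when adjusted over the methionine list alone, pooled (0.44, SE 0.12, adjusted p = 0.0189) and in HT29 (0.72, SE 0.22, adjusted p = 0.0311), but not over all genes (adjusted p = 0.139 and 0.0672). In HT29 it averaged 0.13, 0.85 and -0.35 at 10, 100 and 4000 ng/ml, a change of -1.19 between 100 and 4000 ng/ml (adjusted p = 0.0041).

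Other splits of the samples were counted for the line contrasts in fits of the 2 lines compared. Of 100 splits, only the real one gave as many calls as the real 784 for Caco-2 against CCD841CoTr (highest other 326). The same held for the 479 of HT29 against CCD841CoTr (highest other 168) and the 680 of Caco-2 against HT29 (highest other 134). Every other split mixed arrays of 2 lines, so this outcome could be foreseen. Replicates A and B may not be separate cultures, so the arrays may not be independent. These splits therefore cannot exclude chance for the line counts. For the pooled doses, a fit of line plus dose, run first, gave 0 real calls in each contrast, with 156, 113 and 92 at an unadjusted p under 0.05 for 4000 against 10, 100 against 10 and 4000 against 100 ng/ml. With a real count of 0 that fit cannot test chance (highest other split 36, 7 and 1). In the fit of 9 groups, chosen after that was seen, 6, 28 and 32 of 100 splits gave as many as the real 16, 2 and 4, in the same order (highest other 63, 77 and 57). Chance is not excluded for the pooled dose counts. Splits with several times the real count point to a structure of the samples. For 4000 against 10 and 4000 against 100 ng/ml, the highest one exchanged the doses in CCD841CoTr alone. That split kept the dose groups of each line whole, so it was not a random grouping. It set the CCD841CoTr response against that of the other lines. For 100 against 10 ng/ml the highest split exchanged the doses in Caco-2 and HT29. It also set CCD841CoTr 10 A and 100 A against 10 B and 100 B.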
